A study of Mus musculus with 6 samples.

How the data were processed

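The series comprised 6 Affymetrix Mouse Genome 430 2.0 arrays, which measure transcripts with 3'-biased sets of short oligonucleotide probes. Per the labels' protocols, small intestines of C57BL/6 mouse embryos at embryonic day 18.5 were opened and kept for 9 hours at 4 °C in a solution that releases the epithelium without enzymes, and the detached epithelium and the remaining mesenchyme were collected separately. Tissue of 3 embryos was pooled per sample, 6 pools per tissue were made, and 3 per tissue were chosen for the arrays by RT-PCR for Vil1 and Prkg2 (epithelium) and Vim, Madcam1 and Actg2 (mesenchyme). The labels do not say which embryos gave rise to which pool, so the letters A, B and C were not treated as pairs. The groups, epithelium (A, B, C) and mesenchyme (A, B, C), were taken from the labels.

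The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. The version, the settings and the step between arrays were not given in the sources used here. The values were rounded to 0.1 and ranged from 4.6 to 15.2. The 6 arrays did not share a distribution, with medians from 8.1 to 8.7, as a full quantile step over these arrays would have given. The values carried no detection calls, so that signal near background was not marked. Within a tissue, 5.14% to 12.7% of probe sets had identical rounded values in a pair of arrays, and no array was a copy of another.

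Of 45101 probe sets, 64 controls were set aside and 45037 were tested. The platform annotation used here gave 1 gene symbol for 34945 of them, several for 932 and none for 9160. Symbols were checked against RefSeq gene names of the assembly GRCm38.p6, where 34884 probe sets matched a current symbol, 59 a synonym, and 2 kept the symbol of the annotation. This gave 18161 genes. No coordinates were used. A gene was represented by its probe set with the highest mean over the 6 arrays, and probe sets with several genes were not used for genes. Of 9020 genes with several probe sets, 25 had probe sets that changed in opposite directions. Of 260 genes that the rule for named genes took, 7 were not called by their representative but by another probe set, and the results name them with both values.

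The comparison of epithelium with mesenchyme was made with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes on the deposited values of all 6 arrays, with no further scaling and no covariate, and p-values were adjusted by Benjamini-Hochberg over genes or over probe sets. A gene or probe set was called changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The fit had 4 residual and 31.7 prior degrees of freedom. With values rounded to 0.1, a difference of exactly 1 counted as 2-fold. Fold values were computed from means of log2 values and are understated where one tissue lies near background. The p-values and standard errors rest on the spread between pools within a tissue, drawn by eBayes towards a spread shared over all probe sets. For a gene with widely spread pools, such as Afp (SD of 1.46 in the mesenchyme), the standard error (0.36) is thereby lowered. The pools had been chosen by RT-PCR, so that their spread may differ from that of unselected pools.

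Gene lists for cell types, pathways and families were written before the data were examined, and 48 lists were used, 47 of them with at least 3 measured genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and counts of changed members were also made with p-values adjusted over the list alone. The list of solute carriers, the ribosomal list and other families were taken by symbol patterns. The ribosomal pattern also took genes of Rps6k kinases and of an Rps19-binding protein, the forkhead pattern a noncoding gene next to Foxl2, and the pattern for oxidative phosphorylation assembly factors. The BMP and TGF-beta ligand list held the protease gene Bmp1, and the Wnt antagonist list Ndp, which encodes a pathway activator. The list of BMP and activin antagonists held latent TGF-beta binding proteins (Ltbp) and the intracellular Smad6 and Smad7. The growth factor list held Fgf13, which encodes an intracellular protein. No alternative list left these genes out. The rule for named genes, also fixed before the data were examined, took the 5 RT-PCR genes, the 12 genes with the largest difference in each direction among changed genes without overlap between tissues, leaving out clone names, up to 4 changed genes per list and up to 4 of its minority direction, and all measured Hedgehog, Wnt ligand, secreted Wnt antagonist and BMP genes. Members of gene families in the closing observations fall outside this rule and were chosen after their values were seen.

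RNA quality was examined by the difference between 3' and 5' control probe sets of Gapdh and beta-actin, compared between tissues by exact permutation tests. The same difference for 18S ribosomal RNA was computed after the data had been seen. The steps were tested on simulated data built from the means and spreads of the 18161 genes for the comparison of epithelium with mesenchyme, with 200 genes changed by known amounts. Of 50 genes each changed by a log2 difference of 1, 1.5, 2 and 4, 54%, 86%, 92% and 100% were recovered, and 2 of 17961 unchanged genes were called. A true difference of 1 lies on the cutoff itself, which limits its recovery. The simulated noise was independent between genes and held no offset between arrays. The count of false calls therefore does not cover such offsets or genes that vary together. Alternatives were a replicate block, cyclic loess, arrays centred on spike-in controls, on ribosomal protein genes or on the median, quantile normalization, a filter on dim probe sets, trend and robust eBayes, array weights, treat at 2-fold, no fold minimum, other rules for probe sets, camera with an estimated correlation, fry, lists without shared or misplaced members, and each array left out. Quantile normalization, equal medians, spike-in scaling with mesenchyme B left out, the estimated correlation after quantile normalization and the ribosomal list without kinases were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.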

Results

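Gene expression was measured in the epithelium and in the mesenchyme of the mouse small intestine shortly before birth, when villi are present and the gut wall already holds muscle, vessels and nerves. Each of the 6 arrays carried RNA from 1 pool of tissue from 3 embryos, with 3 arrays for the epithelium (A, B and C) and 3 for the mesenchyme (A, B and C). The stated purpose was to describe the expression profiles of both compartments. The values were log2 expression values per probe set, with medians of 8.1, 8.6 and 8.3 in the epithelial arrays and 8.7, 8.5 and 8.7 in the mesenchymal arrays. The number of arrays limits the precision of each value. Below, a level is the mean ± SD of 3 arrays, a difference is on the log2 scale with its standard error from limma (3 arrays per tissue), and a gene is called changed at an adjusted p under 0.05 with at least a 2-fold difference.

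The tissues differed in the genes of absorption, epithelial junctions and drug metabolism on one side and of contraction, connective tissue and vessels on the other. Clca1, a secreted product of goblet cells, was higher in the epithelium by 6.13 ± 0.29, Abcc2, an export pump for conjugated compounds, by 6.03 ± 0.24, and Pck1, an enzyme of gluconeogenesis, by 6.00 ± 0.26. Myl9, a regulatory light chain of smooth muscle myosin, was higher in the mesenchyme by 7.53 ± 0.27, Actg2, the actin of enteric smooth muscle, by 7.23 ± 0.26, and Col1a1, a chain of type I collagen, by 7.20 ± 0.24. In total, 4380 of 18161 genes changed (24.1%), 1488 of them higher in the epithelium and 2892 higher in the mesenchyme. A difference of 8-fold or more was found for 313 genes higher in the epithelium and 475 higher in the mesenchyme, and one of 32-fold or more for 39 and 77 genes.

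**Figure D1:**
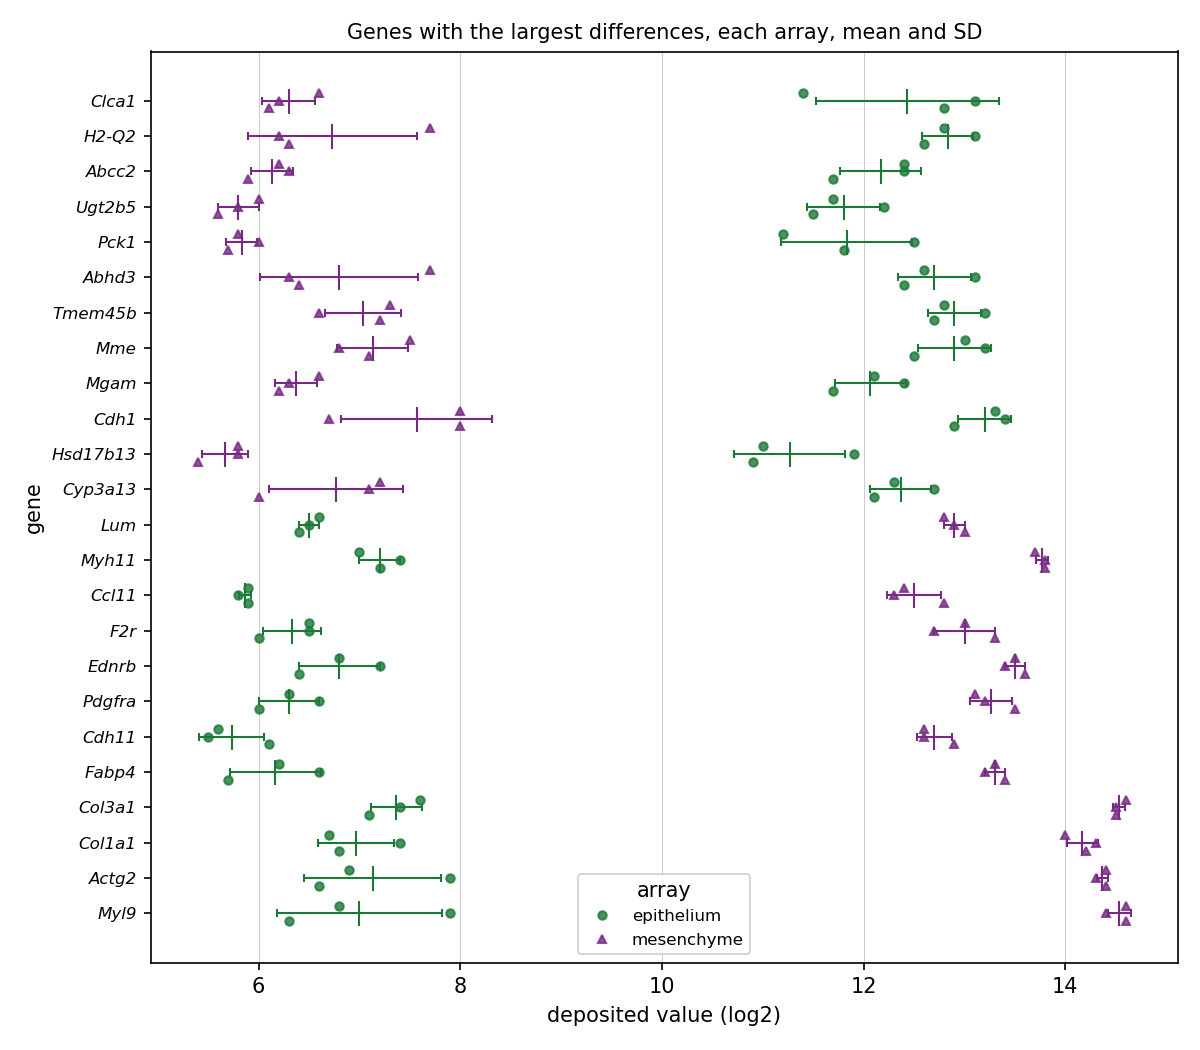
Deposited log2 values (horizontal axis) of the 12 genes with the largest difference in each direction (vertical axis), with a symbol per array (circles, epithelium; triangles, mesenchyme), a tick at the mean and a bar for the SD (n = 3). No array of one tissue overlaps the arrays of the other for these genes; Myl9 lies at 6.3, 7.9 and 6.8 in the epithelium and at 14.6, 14.4 and 14.6 in the mesenchyme.

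The other genes with the largest excess in the epithelium were H2-Q2, a class I histocompatibility gene whose probe set could also read its close paralogs (6.10 ± 0.28), Ugt2b5, a glucuronosyltransferase (6.00 ± 0.24), Abhd3 (5.90 ± 0.28), Tmem45b (5.87 ± 0.24), the membrane peptidase Mme (5.77 ± 0.24), the disaccharidase Mgam (5.70 ± 0.24), the adherens junction cadherin Cdh1 (5.63 ± 0.27), Hsd17b13 (5.6 ± 0.25) and the cytochrome P450 gene Cyp3a13 (5.6 ± 0.26). The corresponding genes of the mesenchyme were Col3a1 (7.17 ± 0.23), the fatty acid-binding protein gene Fabp4 (7.13 ± 0.24), Cdh11, a cadherin of mesenchymal cells (6.97 ± 0.23), the growth factor receptor Pdgfra (6.97 ± 0.23), the endothelin receptor Ednrb (6.70 ± 0.24), the thrombin receptor F2r (6.67 ± 0.24), the chemokine Ccl11 (6.63 ± 0.23), the smooth muscle myosin heavy chain Myh11 (6.57 ± 0.23) and the matrix proteoglycan Lum (6.40 ± 0.22). Adjusted p-values for these 24 genes were 1.50e-19 or lower in limma with Benjamini-Hochberg adjustment, apart from Cdh1 (2.54e-19) and Cyp3a13 (1.51e-19). The values are those of the brightest probe set of each gene. In the mean of a gene's probe sets, the difference was 3.58 for Clca1, 3.48 for Pck1, 2.58 for Hsd17b13, 4.47 for Fabp4, 4.19 for Pdgfra and 3.85 for Myh11. Among all named genes that kept their call, it was more than 1.5 times smaller for 34 and larger for 2. The levels of the 24 genes in the lower tissue ranged from 5.67 (Hsd17b13) to 7.57 (Cdh1), and 15 control probe sets for bacterial transcripts averaged 5.47 to 5.98 per array.

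Arrays of the same tissue correlated at 0.980 on average across probe sets (0.978 to 0.984) and arrays of different tissues at 0.793 (0.773 to 0.813). The first principal component separated the tissues and held 84.4% of the variance, and the second held 8.14%. Of the changed genes, 4336 had arrays that did not overlap between tissues, and so had 46.5% of all genes tested, against 10% from chance with 3 arrays against 3. Probe sets gave 9671 changes among 45037, with 2695 higher in the epithelium and 6976 higher in the mesenchyme (72.1%). The predominance of mesenchymal genes (66.0%) moved with the scaling of the arrays. It was 55.4% after cyclic loess, 53.0% after quantile normalization, 50.7% with the arrays centred on ribosomal protein genes, 49.4% with equal medians and 77.5% with equal hybridization spike-in controls. The median difference over all genes was -0.17 in the deposited values and shifted by 0.21 (loess), 0.27 (quantile), 0.28 (ribosomal), 0.30 (medians) and -0.26 (spike-in) under these scalings. No gene changed in the deposited values changed in the opposite direction under any of these 5 scalings. The spike-in controls averaged 9.80 in mesenchyme B and 10.56 to 10.77 in the other 5 arrays, so that the share and the shift under spike-in scaling rested on 1 array. With mesenchyme B left out, spike-in scaling gave 66.8% and a shift of 0.01. Of the calls named below as ending under spike-in scaling, only that of Tbx15 ended. The calls of Bmp1 (0.99), Nog (0.99), Smad6 (0.95), Smad7 (0.97) and Sufu (0.90), which held under spike-in scaling of all 6 arrays, ended as well.

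The 3' and 5' control probe sets of Gapdh differed by 0.03 ± 0.15 in the epithelium and by -0.03 ± 0.06 in the mesenchyme, and those of beta-actin by 0.33 ± 0.06 and 0.30 ± 0.10. Between tissues, they thus differed by 0.07 and 0.03 (exact permutation tests, two-sided, p = 0.9 and p = 1, where 0.1 is the smallest p that 3 against 3 arrays allow). The 3 control probe sets of 18S ribosomal RNA averaged 13.57, 13.33 and 12.30 in the epithelium and 11.97, 10.77 and 10.03 in the mesenchyme, with SDs of up to 1.21 and 1.61. The 3' probe set of 18S lay above the 5' one by 0.23 ± 0.12 in the epithelium and by 1.20 ± 0.96 in the mesenchyme, where mesenchyme B stood at 2.3.

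The genes that the submitters had measured by RT-PCR to choose the purest of 6 pools per tissue differed in the direction of that choice. Vil1, which encodes the microvillus protein villin (probe set 1448837_at), was at 13.37 ± 0.21 in the epithelium and 8.67 ± 0.55 in the mesenchyme, and Prkg2, a cGMP-dependent kinase (1435460_at), at 12.00 ± 0.30 and 8.80 ± 0.36. Vimentin (Vim, 1450641_at) was at 7.87 ± 0.25 in the epithelium and 13.97 ± 0.06 in the mesenchyme, Actg2 (1422340_a_at) at 7.13 ± 0.68 and 14.37 ± 0.06, and Madcam1, an adhesion molecule of mucosal vessels (1425253_a_at), at 8.0 ± 0.30 and 10.63 ± 0.06. Both epithelial genes and all 3 mesenchymal genes changed, with the same counts adjusted over the list alone, and the mesenchymal list passed camera (adjusted p = 1.41e-08, and adjusted p = 0.197 with an estimated correlation). Because the pools were chosen on these genes, the counts are not independent evidence of direction. Abundant genes of one tissue also gave signal in the other, which without detection calls cannot be told apart from nonspecific signal. Among 58 genes of 4 epithelial lists with an epithelial level of at least 12, the list medians in mesenchyme A, B and C ranged from 4.13% to 13.4% of the epithelial level on the linear scale, and those of 5 mesenchymal lists in epithelium A, B and C ranged from 0.728% (enteric neuron and glia, 1 gene) to 8.49% (haematopoietic and immune, 6 genes) of the mesenchymal level. For 16 smooth muscle genes they were 2.09%, 2.79% and 2.57%, and for 28 matrix genes 4.95%, 5.95% and 5.24%.

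Genes of the absorptive enterocyte were higher in the epithelium. Of 27 measured genes of the brush border and digestive enzymes, 21 were higher in the epithelium and 6 did not change, and the largest differences were those of Mgam, the protease Mep1b (5.33 ± 0.25), the microvillar protocadherin Cdhr2 (5.10 ± 0.24) and Vil1 (4.70 ± 0.25). Of 26 lipid absorption and lipoprotein genes, 21 were higher in the epithelium, among them Apob (5.07 ± 0.25), the core protein of chylomicrons, Mttp (4.40 ± 0.23), which loads lipid onto it, and the apolipoproteins Apoc3 (3.97 ± 0.24) and Apoc2 (3.67 ± 0.25). Scarb1, a lipoprotein receptor, was the member higher in the mesenchyme (1.27 ± 0.24), a call that ended under ribosomal centring and equal medians. Of 26 nutrient transporters, 22 were higher in the epithelium and none was higher in the mesenchyme. Among them were Slc3a1 (5.43 ± 0.25) and Slc7a9 (5.33 ± 0.27), the subunits of the cystine transporter, Slc6a20a (5.30 ± 0.24), a proline carrier, and Slc2a2 (5.10 ± 0.25), a glucose transporter. Of 37 genes of epithelial junctions and keratins, 33 were higher in the epithelium, led by Cdh1, Epcam (4.63 ± 0.24), Cdh17 (4.40 ± 0.24) and the claudin Cldn7 (4.33 ± 0.24). The counts were the same for these 4 lists when adjusted over the list alone. All 4 passed camera (adjusted p = 6.12e-30, 6.61e-25, 4.22e-30 and 1.69e-33, and adjusted p = 0.197 for each with an estimated correlation).

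**Figure D2:**
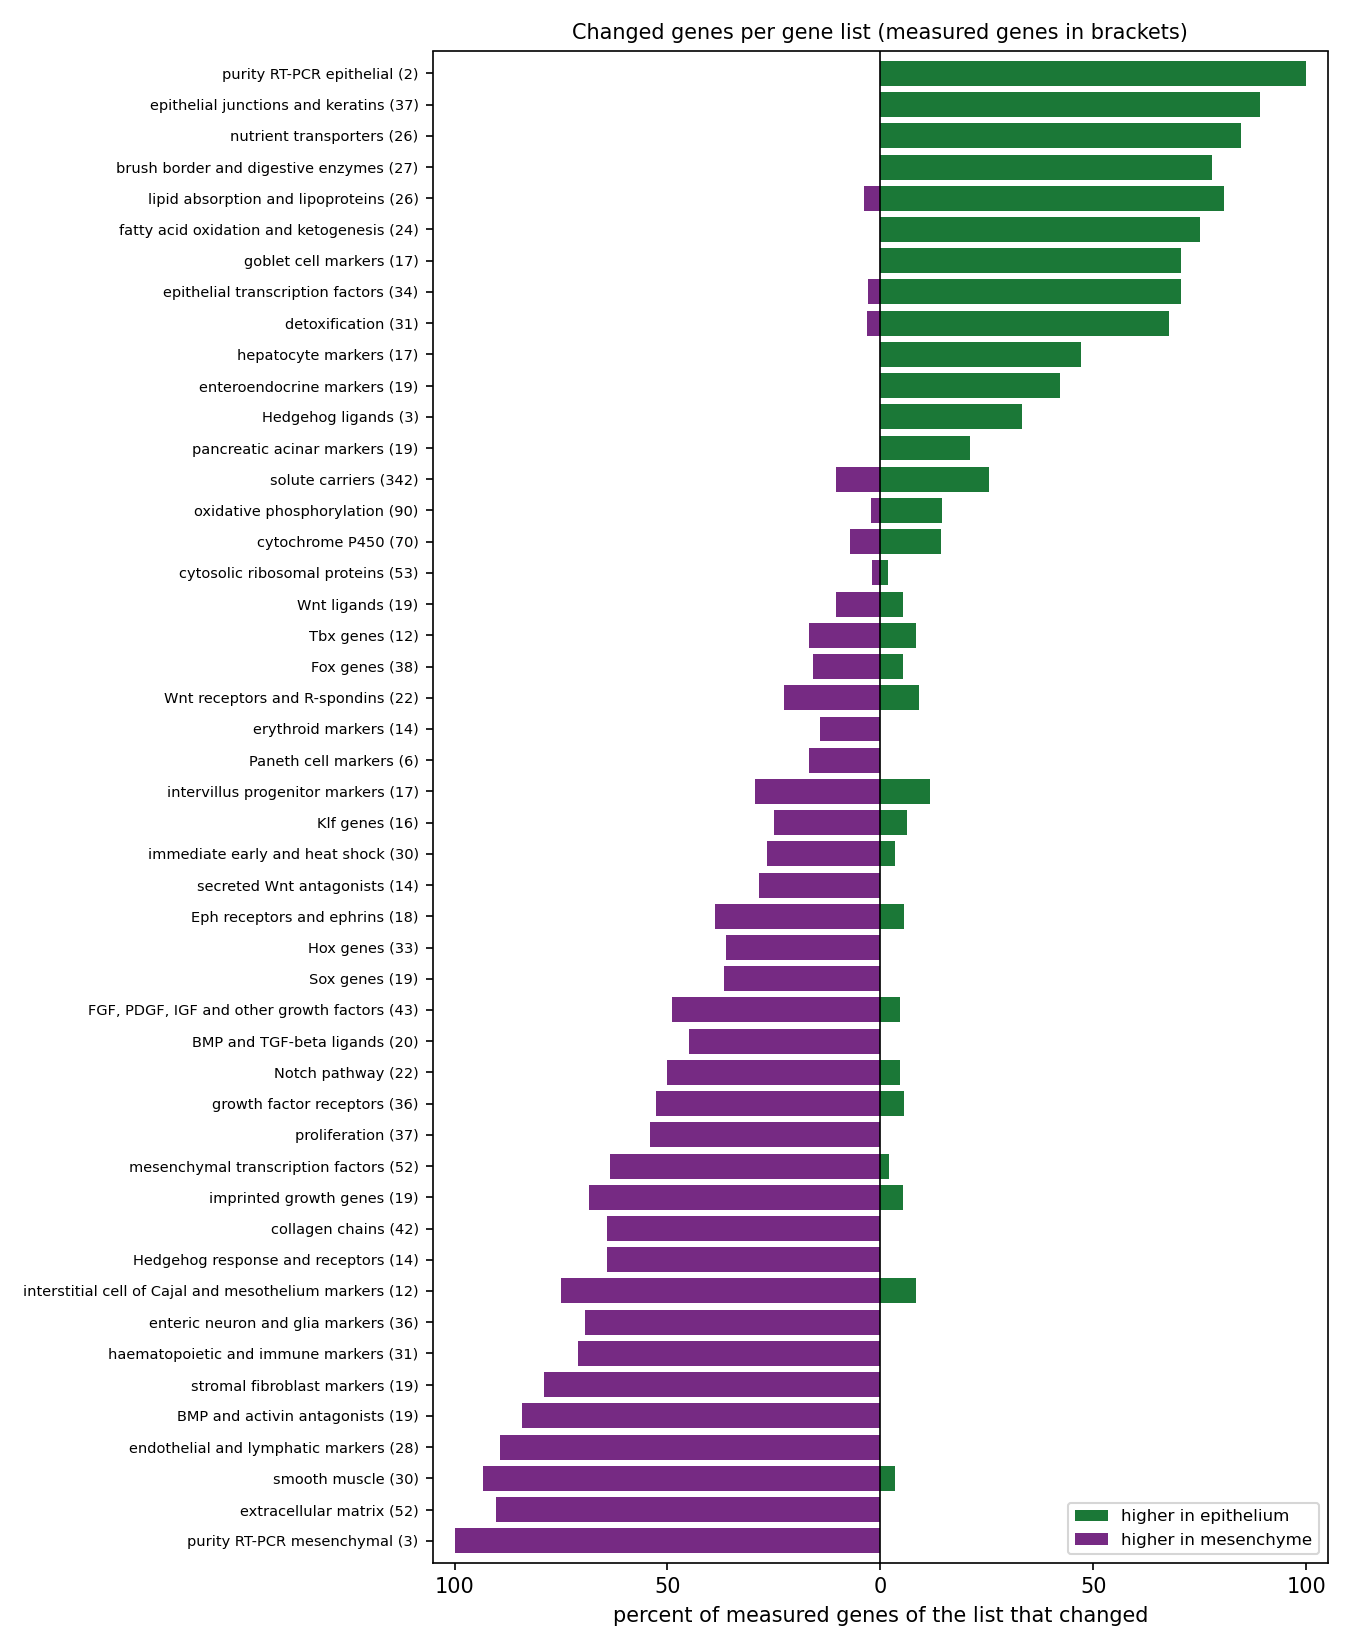
Percent of the measured genes of each list (number in brackets) that were higher in the epithelium (green, to the right) or higher in the mesenchyme (purple, to the left). The list of epithelial junctions and keratins has 33 of 37 genes higher in the epithelium, and the extracellular matrix list has 47 of 52 higher in the mesenchyme.

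Among markers of secretory cells, those of goblet cells and some enteroendocrine hormones were higher in the epithelium. Of 17 goblet cell genes, 12 were higher there, including Clca1, Muc13, a membrane mucin (3.90 ± 0.23), the protease inhibitor Spink4 (3.90 ± 0.24) and Agr2, which assists mucin folding (3.87 ± 0.30). Of 19 enteroendocrine genes, 8 were higher in the epithelium, among them the hormone genes Cck (4.20 ± 0.24), Gcg (3.43 ± 0.27), Nts (2.90 ± 0.25) and Gip (2.83 ± 0.24), and 11 did not change. Both lists passed camera (adjusted p = 2.37e-13 for goblet cells and 4.67e-07 for enteroendocrine cells, and adjusted p = 0.211 and 0.302 with an estimated correlation). The 17 intervillus progenitor genes went both ways. Olfm4 was higher in the epithelium by 5.33 ± 0.26 and the ubiquitin ligase Rnf43 by 1.47 ± 0.24, while 5 genes were higher in the mesenchyme, among them Cd44 (3.47 ± 0.23), Cdk6 (2.63 ± 0.24) and Smoc2 (2.47 ± 0.24), and the list did not pass (adjusted p = 0.859). Of 6 measured Paneth cell genes, 5 did not change. The call of Lyz1, higher in the mesenchyme by 2.60 ± 0.23, rested on a probe set that can also read its paralog Lyz2, a gene of macrophages, and with such probe sets avoided the difference was 0.23 in favour of the epithelium, which did not pass. The Paneth list did not pass (adjusted p = 0.898). When adjusted over the list alone, the counts of these 4 lists were the same.

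Transcription factors of gut epithelium and genes of fat oxidation and detoxification were examined next. Of 34 transcription factors known from gut epithelium, 24 were higher in the epithelium, among them Klf5 (3.77 ± 0.24), the bile acid receptor Nr1h4 (3.67 ± 0.24), Gata6 (3.63 ± 0.23) and Creb3l3 (3.50 ± 0.23). Id1, a helix-loop-helix inhibitor, was higher in the mesenchyme (1.03 ± 0.23). This call ended under 4 scalings, all but that on spike-in controls, and without epithelium A, epithelium C or mesenchyme C. Of 24 genes of fatty acid oxidation and ketogenesis, 18 were higher in the epithelium, including the peroxisomal enzyme Ehhadh (4.60 ± 0.25), Acot1 (3.03 ± 0.24), Acsl5 (3.03 ± 0.23) and Hadh (2.30 ± 0.23). Of 31 detoxification genes, 21 were higher in the epithelium, led by Abcc2, Ugt2b5, the sulfotransferase Sult1d1 (5.50 ± 0.26) and the carboxylesterase Ces2e (5.10 ± 0.24), and the aldehyde dehydrogenase Aldh1a1 was higher in the mesenchyme (1.17 ± 0.25), though not under ribosomal centring, equal medians or without epithelium C. Camera gave adjusted p-values of 1.01e-18, 5.02e-12 and 1.10e-19 for these 3 lists (adjusted p = 0.221, 0.299 and 0.197 with an estimated correlation). Counts adjusted over the list alone were equal to these for all these lists.

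Muscle, matrix and fibroblast genes were higher in the mesenchyme. Of 30 smooth muscle genes, 28 were higher there, with Myl9, Actg2, Myh11 and the actin-binding protein gene Tagln (6.13 ± 0.23) in front. Ldb3, a protein of the muscle Z-disc, was higher in the epithelium (1.37 ± 0.25) by 1 of its 3 probe sets. The call ended in their mean (0.78). Of 52 extracellular matrix genes, 47 were higher in the mesenchyme and none in the epithelium, among them Col1a1, Col3a1, Lum and Col6a1 (5.53 ± 0.23). Of 42 collagen chains, 27 were higher in the mesenchyme and 15 did not change, and Col6a4 differed by 5.27 ± 0.23. Of 19 stromal fibroblast markers, 15 were higher in the mesenchyme, including Pdgfra and Vim (6.10 ± 0.23). The 4 lists passed camera (adjusted p = 1.04e-31 for smooth muscle, 2.96e-45 for the matrix, 1.07e-17 for collagen chains and 3.11e-19 for fibroblasts, and adjusted p = 0.197 for each with an estimated correlation). The counts were the same for all these lists when adjusted over the list alone.

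Markers of vessels, enteric nerves and immune cells were higher in the mesenchyme, whereas the erythroid list did not pass. Of 28 endothelial and lymphatic genes, 25 were higher in the mesenchyme, among them Plvap (5.6 ± 0.24), a protein of fenestrated capillaries, the lymphatic receptor Lyve1 (5.23 ± 0.26), Cd93 (4.73 ± 0.23) and the angiopoietin receptor Tek (4.50 ± 0.24). Of 36 enteric neuron and glia genes, 25 were higher in the mesenchyme, including Ednrb, Uchl1 (5.17 ± 0.23), the neuropeptide gene Vip (5.07 ± 0.24) and Fabp7, a marker of glia (4.57 ± 0.25). Of 31 haematopoietic and immune genes, 22 were higher in the mesenchyme, such as the complement gene C1qb (4.80 ± 0.23), the leukocyte phosphatase Ptprc (4.40 ± 0.23), the class II gene H2-Aa (4.37 ± 0.23) and Coro1a (4.37 ± 0.24). Of 12 markers of interstitial cells of Cajal and mesothelium, 9 were higher in the mesenchyme, including Gpm6a (3.43 ± 0.23), the receptor Kit (3.27 ± 0.25) and Lrrn4 (2.67 ± 0.23), while the keratin Krt19, also made by epithelium, was higher there (2.77 ± 0.23). Camera passed all 4 (adjusted p = 1.81e-24, 1.56e-15, 1.29e-13 and 0.000367, and adjusted p = 0.197, 0.197, 0.226 and 0.302 with an estimated correlation), and the last did not pass when dim probe sets were left out (adjusted p = 0.0989). Of 14 erythroid genes, Alas2, of haem synthesis (1.70 ± 0.24), and Car2 (1.90 ± 0.23), a carbonic anhydrase not specific to red cells, were higher in the mesenchyme, and the list did not pass (adjusted p = 0.867). When adjusted over the list alone, the counts of these 5 lists were the same.

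Genes typical of neighbouring organs were examined for tissue taken along at dissection. Of 17 hepatocyte genes, 8 were higher in the epithelium, among them Afp (5.07 ± 0.36), the urea cycle enzyme Cps1 (4.40 ± 0.25), Serpina1b (3.50 ± 0.27) and Fga (3.17 ± 0.24), several of which fetal gut epithelium also makes, and 9 did not change. This list passed camera (adjusted p = 1.79e-05, and adjusted p = 0.359 with an estimated correlation). Of 19 pancreatic acinar genes, 4 were higher in the epithelium, Zg16 (2.10 ± 0.23), Clps (1.90 ± 0.30), Cela1 (1.87 ± 0.24) and Rnase1 (1.63 ± 0.25), and the list did not pass (adjusted p = 0.0885); it passed without epithelium B (adjusted p = 0.0476) and without mesenchyme A (adjusted p = 0.0323). Zg16 is also a goblet cell gene. Counts adjusted over the list alone were equal to these for both lists.

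Of 3 Hedgehog ligands, 1 was higher in the epithelium, and 9 of 14 receptors, mediators and targets were higher in the mesenchyme. Ihh, which encodes Indian hedgehog, was higher in the epithelium by 1.5 ± 0.23 (10.00 ± 0.30 against 8.50 ± 0.20, adjusted p = 1.40e-06). Shh was at 9.33 ± 0.15 in the epithelium and 8.87 ± 0.29 in the mesenchyme (adjusted p = 0.108) and Dhh at 7.83 ± 0.12 and 8.50 ± 0.17 (adjusted p = 0.0164), neither with a 2-fold difference. None of the receptors, mediators and targets was higher in the epithelium. Those higher in the mesenchyme were the receptor Ptch1 (4.80 ± 0.26), the forkhead gene Foxf2 (4.20 ± 0.24), the ligand-binding proteins Hhip (3.83 ± 0.25), Gas1 (3.60 ± 0.23) and Cdon (1.67 ± 0.23), the transcription factors Gli3 (2.70 ± 0.23), Gli1 (2.63 ± 0.23) and Gli2 (1.80 ± 0.23), and Sufu (1.00 ± 0.24), which fell short of 2-fold under 4 of the 5 scalings and without epithelium A, mesenchyme A or mesenchyme B. The other probe set of Cdon differed by 0.07 towards the epithelium. In the mean of their probe sets Cdon (0.80) and Sufu (0.42) lost the call. The list passed camera (adjusted p = 1.52e-07, and adjusted p = 0.221 with an estimated correlation), whereas the 3 ligands did not (adjusted p = 0.371). By the brightest probe set, Foxf1 differed by 0.80 ± 0.22 towards the mesenchyme, Smo by 0.77 ± 0.23, Boc by 0.70 ± 0.23, Foxl1 by 0.53 ± 0.23 and Kif7 by 0.20 ± 0.23, none of them called. A second probe set gave a call for 3 of these genes, higher in the mesenchyme by 4.63 for Foxf1, 2.27 for Smo and 2.37 for Boc. The counts were the same for both lists when adjusted over the list alone.

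**Figure D3:**
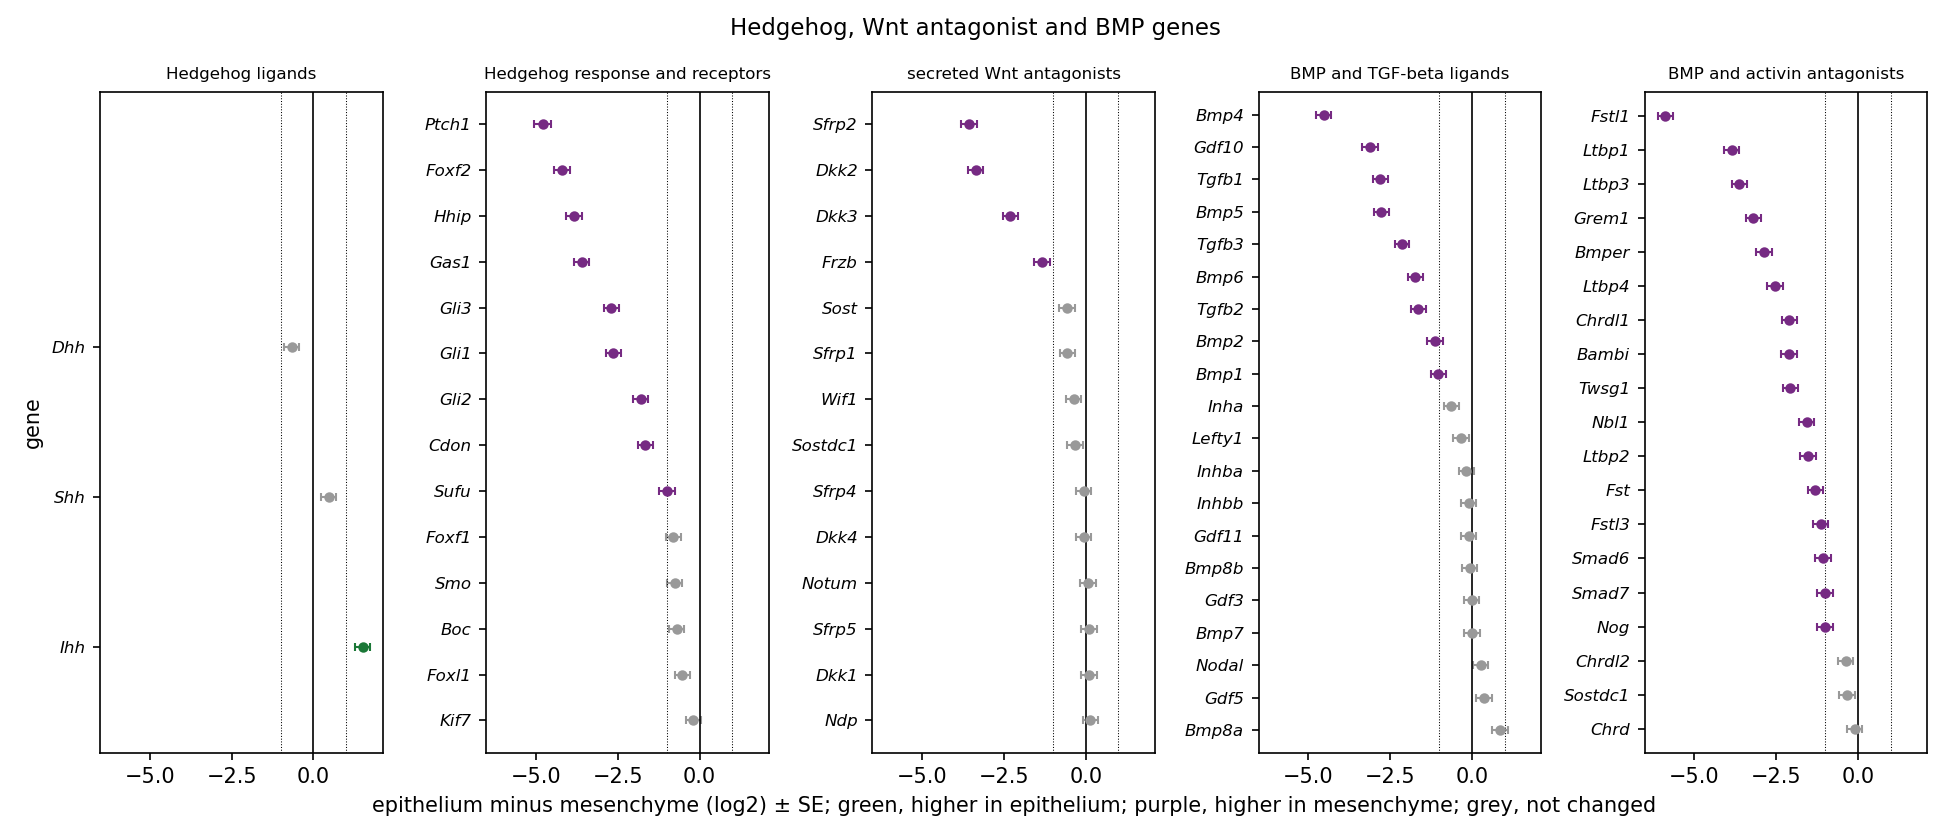
Differences between epithelium and mesenchyme on the log2 scale with their standard errors (limma, 3 arrays per tissue; left of 0, higher in mesenchyme) for the genes of 5 signalling lists, by the brightest probe set of each gene; dotted lines mark 2-fold. Ihh lies at 1.5 and Ptch1 at -4.80, and in the panel of BMP and activin antagonists 16 of 19 genes were called, all on the mesenchymal side.

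Few Wnt ligands differed between the tissues, while several secreted antagonists were higher in the mesenchyme. Of 19 Wnt ligands, Wnt4 (1.37 ± 0.23) and Wnt9a (1.13 ± 0.25) were higher in the mesenchyme and Wnt8b (1.00 ± 0.25) in the epithelium. The Wnt9a call ended under 4 scalings and the Wnt8b call under spike-in scaling. Both ended with array weights, without epithelium C, without mesenchyme A and in the mean of their probe sets (0.33 and 0.22). For Wnt5a the brightest probe set showed no difference (8.80 ± 0.26 against 8.60 ± 0.26, adjusted p = 0.536), but the other 3 were higher in the mesenchyme by 3.93, 3.00 and 2.13. The other 15 ligands differed by 0.70 or less, Wnt10b by 0.70 and Wnt3a by 0.67, and were not called. Of 14 genes of the list of secreted antagonists, Sfrp2 (3.57 ± 0.23), Dkk2 (3.37 ± 0.23), Dkk3 (2.30 ± 0.24) and Frzb (1.33 ± 0.23) were higher in the mesenchyme and none in the epithelium. The Frzb call ended under quantile normalization and in the mean of its probe sets (0.97). The brightest probe set of Sfrp1 differed by 0.57 ± 0.23 towards the mesenchyme and was not called, whereas its other 4 probe sets were higher there by 2.40 to 6.30. That of Sostdc1 differed by 0.33 ± 0.24, and its other probe set by 2.60 towards the mesenchyme. The remaining genes of this list, Sost, Wif1, Sfrp4, Sfrp5, Dkk1, Dkk4, Notum and Ndp, differed by 0.57 or less. Ndp encodes a secreted activator of the pathway and is no antagonist. Of 22 Wnt receptors and R-spondins, Fzd5 (2.47 ± 0.24) and Lgr4 (1.20 ± 0.24) were higher in the epithelium. Lgr4 was not called under spike-in scaling, without epithelium B or in the mean of its probe sets (0.77). Another 5 were higher in the mesenchyme, among them Fzd1 (3.00 ± 0.23), Fzd2 (2.63 ± 0.23) and Rspo1 (2.00 ± 0.23). None of these 3 lists passed camera (adjusted p = 0.837 for ligands, 0.0748 for antagonists and 0.673 for receptors). The antagonist list did pass camera with the mean of each gene's probe sets (adjusted p = 0.00261) and with probe sets able to read several transcripts avoided (adjusted p = 0.0126). Over the 5 scalings, 3 to 7 of the receptors and R-spondins were higher in the mesenchyme and 1 to 3 in the epithelium. When adjusted over the list alone, the counts of all these lists were the same.

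Of the BMP and TGF-beta families, 9 of 20 genes of the ligand list and 16 of 19 of the antagonist list were higher in the mesenchyme. The antagonist list also holds latent TGF-beta binding proteins (Ltbp), which are no BMP or activin antagonists, and the intracellular inhibitors Smad6 and Smad7. Bmp4 was at 12.33 ± 0.21 in the mesenchyme and 7.80 ± 0.10 in the epithelium, a difference of 4.53 ± 0.23 (adjusted p = 8.21e-19). Gdf10 (3.10 ± 0.24), Tgfb1 (2.80 ± 0.23), Bmp5 (2.77 ± 0.24), Tgfb3 (2.13 ± 0.23), Bmp6 (1.73 ± 0.23), Tgfb2 (1.63 ± 0.23), Bmp2 (1.13 ± 0.25) and Bmp1 (1.03 ± 0.23) followed, with Bmp2 and Bmp1 losing the call under 4 scalings and without epithelium A or mesenchyme A. Bmp1, despite its name, encodes a protease and is no ligand of these families. No ligand was called higher in the epithelium. Bmp8a differed by 0.87 ± 0.24 towards the epithelium, short of 2-fold except under 4 scalings, and Bmp7 showed no difference by its brightest probe set (10.00 in both tissues), while another of its probe sets was higher in the epithelium by 2.23. None of the genes of the antagonist list was higher in the epithelium, and those higher in the mesenchyme included the follistatin-like gene Fstl1 (5.90 ± 0.23), the TGF-beta binding proteins Ltbp1 (3.87 ± 0.23) and Ltbp3 (3.63 ± 0.23), Grem1 (3.20 ± 0.23), Bmper (2.87 ± 0.24) and Chrdl1 (2.10 ± 0.23). Noggin (Nog) and Smad7 reached exactly 2-fold (1.00 ± 0.24 for each) and lost the call, with Fstl3 and Smad6, under 4 scalings. Nog also lost it with array weights and without epithelium A, epithelium C or mesenchyme A. Smad7 lost it in the mean of its probe sets (0.68) and without epithelium A or mesenchyme A, and Smad6 without epithelium A, epithelium C or mesenchyme B. The ligand list passed camera (adjusted p = 0.00749, and adjusted p = 0.553 with an estimated correlation) but not without epithelium B (adjusted p = 0.0600). The antagonist list passed as well (adjusted p = 9.62e-09, and adjusted p = 0.221 with an estimated correlation). Counts adjusted over the list alone were equal to these for all these lists.

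Growth factors, their receptors and Notch genes included members higher in the mesenchyme and a few higher in the epithelium. Of 43 genes of the list of further growth factors, 21 were higher in the mesenchyme. Among them were Fgf13 (5.53 ± 0.23), the chemokine Cxcl12 (5.37 ± 0.23), Ccn2 (4.43 ± 0.23) and the guidance factor Ntn1 (4.07 ± 0.23). Fgf13, despite its name, encodes an intracellular protein and no secreted ligand. Fgf15, a hormone of the ileal epithelium (1.57 ± 0.31), and the EGF-family ligand Hbegf (1.03 ± 0.24) were higher in the epithelium. Hbegf was not called under spike-in scaling, with array weights, without epithelium B or mesenchyme C, or in the mean of its probe sets (0.67). Of 36 growth factor receptors and IGF-binding proteins, 19 were higher in the mesenchyme, with Igfbp7 (5.20 ± 0.23) and Igfbp3 (5.10 ± 0.23) next to Pdgfra and Ednrb, and Erbb3 (2.03 ± 0.23) and Acvr2a (1.13 ± 0.24) were higher in the epithelium. Acvr2a was not called under spike-in scaling or in the mean of its probe sets (0.72). Of 22 Notch pathway genes, 11 were higher in the mesenchyme, including Dlk1 (5.30 ± 0.23), Jag1 (2.90 ± 0.23), Notch4 (2.70 ± 0.25) and Notch2 (2.63 ± 0.23), and Hes6 was higher in the epithelium (1.10 ± 0.23), again not under spike-in scaling. The Dlk1 call rested on a probe set able to read several transcripts. With such probe sets avoided, Dlk1 (0.77) and Hes6 (0.87) were not called. Notch4 was called by 1 of its 3 probe sets. In the mean of their probe sets Notch4 (0.79) and Hes6 (0.98) lost the call. These 3 lists passed camera (adjusted p = 5.57e-06, 3.51e-07 and 0.000570, and adjusted p = 0.471, 0.359 and 0.359 with an estimated correlation). Of 18 Eph receptors and ephrins, 7 were higher in the mesenchyme, such as Epha7 (2.27 ± 0.24), Ephb3 (1.67 ± 0.23) and Efna5 (1.63 ± 0.23), and Epha1 was higher in the epithelium (1.87 ± 0.24) by 1 of its 3 probe sets. The Epha1 call ended in their mean (0.66), and the list did not pass (adjusted p = 0.234). From 4 to 10 Eph receptors and ephrins were higher in the mesenchyme over the 5 scalings, and from 1 to 5 of the growth factor receptors were higher in the epithelium. The counts were the same for all these lists when adjusted over the list alone.

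Regulators of the mesenchyme formed a further group. Of 52 transcription factors known from mesenchyme, 33 were higher in the mesenchyme, led by Tcf21 (6.37 ± 0.23), Snai2 (5.80 ± 0.23), Foxf2 and Hand2 (4.07 ± 0.24), and Osr2 was higher in the epithelium (1.57 ± 0.31). The Osr2 call ended without epithelium B (0.95) and in the mean of its 2 probe sets (0.82), the other of which differed by 0.07. The list passed camera (adjusted p = 4.50e-13, and adjusted p = 0.226 with an estimated correlation). Of 33 Hox genes, 12 were higher in the mesenchyme and none in the epithelium, among them Hoxc8 (4.33 ± 0.23), Hoxb6 (3.37 ± 0.23), Hoxa2 (3.13 ± 0.25) and Hoxb5 (2.93 ± 0.23), and this list passed as well (adjusted p = 0.00665, and adjusted p = 0.551 with an estimated correlation). Of 19 Sox genes, 7 were higher in the mesenchyme, including Sox18 (3.50 ± 0.24), Sox11 (3.17 ± 0.23), Sox7 (2.70 ± 0.23) and Sox4 (2.63 ± 0.24), with an adjusted p of 0.0263 for the list (adjusted p = 0.551 with an estimated correlation). The Sox list lost its call under 4 of 5 scalings (adjusted p of up to 0.132) and without epithelium A (0.0806) or epithelium B (0.190), with array weights (0.0518), with a replicate block (0.0958) and without members of several lists (0.241). Of 38 Fox genes, Foxa1 (2.53 ± 0.24) and Foxa3 (1.67 ± 0.24) were higher in the epithelium and 6 in the mesenchyme, such as Foxf2, Foxp2 (2.67 ± 0.24) and Foxc2 (2.17 ± 0.24). Of 12 Tbx genes, Tbx2 (3.17 ± 0.24) and Tbx1 (1.70 ± 0.24) were higher in the mesenchyme and Tbx15 (1.00 ± 0.23) in the epithelium. The Tbx15 call ended under spike-in scaling, with array weights, without epithelium B, epithelium C or mesenchyme B and in the mean of its probe sets (0.40). With probe sets able to read several transcripts avoided, the difference was -0.20. Of 16 Klf genes, Klf5 was higher in the epithelium, and Klf2 (2.40 ± 0.23), Klf12 (1.40 ± 0.23) and Klf11 (1.13 ± 0.24) were among 4 higher in the mesenchyme, Klf11 not under the 4 scalings other than that on spike-in controls. From 2 to 5 Klf genes were higher in the mesenchyme over the 5 scalings, and from 3 to 6 with single arrays left out. The Fox, Tbx and Klf lists did not pass (adjusted p = 0.502, 0.657 and 0.477). When adjusted over the list alone, the counts of these 6 lists were the same.

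**Figure D4:**
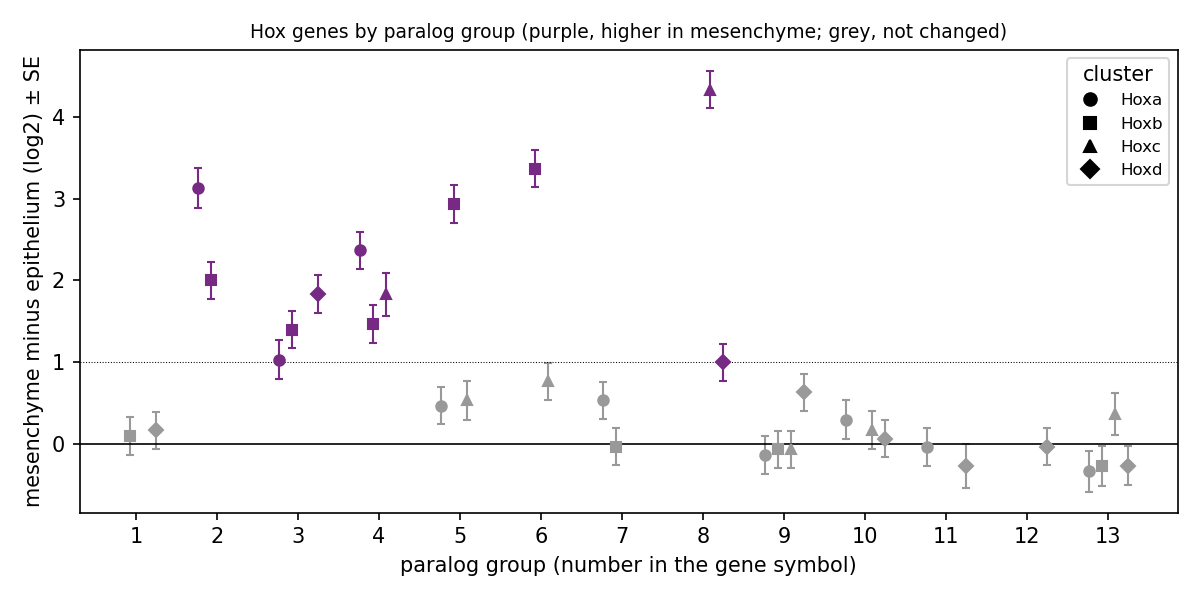
Differences between mesenchyme and epithelium on the log2 scale with their standard errors (limma, 3 arrays per tissue; above 0, higher in mesenchyme) of 33 Hox genes by paralog group (horizontal axis), with a symbol per cluster; purple, called higher in the mesenchyme. Hoxc8 lies at 4.33, and all 12 genes called lie in groups 1 to 8.

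Large gene families held members of both kinds. Of 342 solute carriers, 87 were higher in the epithelium and 36 in the mesenchyme. The latter included Slc44a2 (3.60 ± 0.24), Slc38a4 (3.43 ± 0.23), the glucose transporter Slc2a3 (3.20 ± 0.23, and 1.07 with probe sets able to read several transcripts avoided) and the mitochondrial ADP/ATP carrier Slc25a4 (2.93 ± 0.23). The list passed camera towards the epithelium (adjusted p = 3.50e-06, and adjusted p = 0.629 with an estimated correlation) but not fry (adjusted p = 0.0592), and its median of 0.13 became -0.13 under spike-in scaling of all 6 arrays. Of 70 cytochrome P450 genes, many with close paralogs that a probe set may not tell apart, 10 were higher in the epithelium, among them Cyp3a13, Cyp2c65 (4.00 ± 0.24), Cyp2d26 (3.50 ± 0.25) and Cyp2c68 (3.37 ± 0.24). A further 5 were higher in the mesenchyme, such as Cyp7b1 (3.27 ± 0.24), Cyp1b1 (1.90 ± 0.23), Cyp20a1 (1.57 ± 0.26) and Cyp3a11 (1.33 ± 0.23), and 5 to 8 were over the 5 scalings. That list had an adjusted p of 0.0145 (adjusted p = 0.705 with an estimated correlation) and of 0.145 with fry, and its median of 0.03 fell to -0.23 under spike-in scaling of all 6 arrays. Of 90 genes of oxidative phosphorylation and its assembly, 13 were higher in the epithelium, including Cox7a1 (2.20 ± 0.24) and Uqcrq (1.57 ± 0.23), the latter by 1 of its 4 probe sets and not in their mean (0.16). Ndufa4l2 (2.43 ± 0.22) and Cox6b2 (1.57 ± 0.23) were higher in the mesenchyme, and 75 genes did not change. The list median was 0.52 towards the epithelium (adjusted p = 2.67e-05, and adjusted p = 0.663 with an estimated correlation), and the number of genes higher in the epithelium ranged from 5 to 28 over the 5 scalings. Of 53 genes taken by the ribosomal protein pattern, Rps4l was higher in the epithelium (1.00 ± 0.23), not under spike-in scaling, with array weights or without epithelium B or mesenchyme C. The kinase gene Rps6ka3, which is no ribosomal protein, was higher in the mesenchyme (1.23 ± 0.24), not under ribosomal centring, equal medians or in the mean of its probe sets (0.82). With other scalings or single arrays left out, 0 to 2 genes were higher in the epithelium and 0 to 5 in the mesenchyme. The ribosomal list did not pass (adjusted p = 0.787), except towards the mesenchyme after cyclic loess (adjusted p = 0.00386) and quantile normalization (0.00899). Counts adjusted over the list alone were equal to these for these 4 lists.

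Proliferation genes and imprinted growth genes were called higher in the mesenchyme or not at all, with 1 exception. Of 37 proliferation genes, 20 were higher there and none in the epithelium, among them Ccne2 (2.73 ± 0.24), Ccnd1 (2.30 ± 0.23), Bub1 (2.07 ± 0.27) and the replication factor Mcm4 (2.03 ± 0.26, and 1.03 with probe sets able to read several transcripts avoided). The list passed camera (adjusted p = 4.47e-05, and adjusted p = 0.621 with an estimated correlation), and the number of genes higher in the mesenchyme ranged from 10 to 27 over the 5 scalings. Of 19 imprinted growth genes, 13 were higher in the mesenchyme, including Mest (5.77 ± 0.24), Dlk1 (by 1 of its 2 probe sets, as above), the proteoglycan gene Dcn (4.17 ± 0.23) and Peg3 (4.13 ± 0.25), with an adjusted p of 1.63e-08 (adjusted p = 0.312 with an estimated correlation). The growth inhibitor Cdkn1c was higher in the epithelium (1.07 ± 0.23), a call that ended under spike-in scaling and quantile normalization and without epithelium B or mesenchyme C. Of 30 immediate early and heat shock genes, 8 were higher in the mesenchyme, among them the chaperones Hspa1a (3.77 ± 0.23), Hspa1b (3.37 ± 0.31) and Hspb1 (2.87 ± 0.22) and the phosphatase Dusp1 (3.27 ± 0.28). Zfp36, an mRNA-destabilizing protein, was higher in the epithelium (1.10 ± 0.23), not under spike-in scaling or without epithelium B. The list had an adjusted p of 0.0462 (adjusted p = 0.759 with an estimated correlation) and lost its call under 4 of 5 scalings and without any single array except mesenchyme C (adjusted p of 0.0508 to 0.128). It also lost the call with a replicate block (0.0963), array weights (0.0763) or without dim probe sets (0.137). The counts were the same for these 3 lists when adjusted over the list alone.

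In total, 34 of the 47 lists tested passed camera with the preset correlation, 13 towards the epithelium and 21 towards the mesenchyme. With a correlation estimated from the data, which had a median of 0.406 over the lists, none passed (camera with Benjamini-Hochberg adjustment, lowest adjusted p = 0.197, 10 lists at an unadjusted p under 0.05), while fry passed 36. After quantile normalization, tried once the data had been seen, 14 lists passed with an estimated correlation (camera, lowest adjusted p = 0.0389). The failure of all lists thus held for the deposited values, whose arrays had unequal medians. Fry, which compares a list with no change and not with the other genes, passed the secreted Wnt antagonists (adjusted p = 0.00266), Hedgehog ligands (0.0340), Eph receptors and ephrins (0.0322) and Tbx genes (0.0354), which camera did not pass. In the 9 other splits of the 6 arrays into 3 and 3, camera with the preset correlation passed 14 to 31 lists, and limma called no gene. Each of these splits put arrays of both tissues into each group. The tissue difference thus stayed partly in the contrast and otherwise widened the spread within groups. These counts therefore do not show what chance alone would give. In the median, mean and test of a list the sign differed for the Wnt ligands (median -0.10, mean -0.14, test towards the epithelium) and for the Paneth cell genes (median 0.08, mean -0.31).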

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

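Quantile normalization, alone and with an estimated correlation, equal medians, spike-in scaling without mesenchyme B and the kinase-free ribosomal list were tried only after the data were seen; the other alternatives were fixed before. Over the scalings, the filter on dim probe sets, trend and robust variances, array weights, the rules for probe sets and each array left out, the number of changed genes ranged from 3417 to 5004, against 4380. Those with a fold criterion of another kind differed by construction. With treat at 2-fold, 2344 genes changed (815 higher in the epithelium, 1529 in the mesenchyme) and 4726 probe sets (1371 and 3355). With no fold minimum, 7490 genes changed (2513 and 4977) and 16887 probe sets (4839 and 12048). Without dim probe sets, fewer were tested, and 6002 probe sets changed, 3944 of them higher in the mesenchyme, while the mean correlation of arrays of a tissue was 0.9730. With equal medians, 4100 probe sets were higher in the epithelium, since that scaling moves the epithelial arrays up. With each array left out in turn, 4157 to 4764 genes changed, 1265 to 1666 of them higher in the epithelium and 2491 to 3499 in the mesenchyme. Without epithelium A, 59.9% of the changed genes were higher in the mesenchyme, and without epithelium B, 73.5%. Spike-in scaling without mesenchyme B gave 4306 changed genes and 33 lists, the immediate early and heat shock list not among them (adjusted p = 0.0739). The 6 named genes that lost their call there were Bmp1, Nog, Smad6, Smad7, Sufu and Tbx15.

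Camera with an estimated correlation passed 0 of 47 lists (10 at an unadjusted p under 0.05), because it widens the null by correlations far above the preset one, and fry passed 36. The estimated correlations were taken from the deposited values, whose arrays had unequal medians. After quantile normalization, 14 lists passed camera with an estimated correlation (lowest adjusted p = 0.0389), so that this result depended on the scaling. The single arrays left out gave 32 to 34 lists. The fit with array weights stopped before its convergence tolerance was reached, and it passed 32 lists.

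Of the 260 named genes, 4 with a call before or after changed sign under a rule for probe sets, because another probe set then stands for the gene or joins its mean. With probe sets able to read several transcripts avoided, Lyz1 was at 0.2333 (adjusted p = 0.485), Tbx15 at -0.2000 (adjusted p = 0.552) and Uqcrq at -0.1667 (adjusted p = 0.611), and with the mean of all its probe sets Wnt5a was at -2.2167 (adjusted p = 5.02e-23). Without a call in either, Dkk1 (-0.13), Sfrp5 (-0.30), Wnt7b (-0.05) and Wnt9b (-0.05) also changed sign in that mean, and so did 7 to 14 named genes without a call under each of the 5 scalings. In that mean, 237 of the named genes stayed on the same side of the threshold without such a reversal of a call, and 246 to 249 did so under each of the 5 scalings. With single arrays left out, 3 to 7 named genes lost their call, among them Osr2 without epithelium B.

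A replicate block by letter, although the labels pair no samples, gave 4363 changed genes (1482 higher in the epithelium, 2881 in the mesenchyme), 9579 probe sets and 32 lists, and the calls of all 260 named genes were the same. Deviations of samples with the same letter from their tissue means correlated at -0.311, -0.151 and 0.12, so that the data gave no sign of paired samples. Signal near the bacterial controls limits the folds of genes that are low in one tissue.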

Other observations

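The tests on gene families, on mesenchyme C, on heat shock genes and on the order of Hox genes were chosen after the results were seen, and so were spike-in scaling without mesenchyme B and the choice of scalings for the test of an offset. The test with equal medians was chosen after the medians of the arrays were seen. Families defined by the letters that open a gene symbol showed further groups. Of 243 families with at least 10 genes, 8 held more genes higher in the epithelium than the rest of the genes did, and 6 more genes higher in the mesenchyme (Fisher's exact test, one-sided, 486 tests adjusted together). This test takes genes as independent, which members of a family are not, so that its p-values are too low where they vary together. In the epithelium, 4 families passed in the deposited values, under each of the 5 scalings, adjusted anew, and with each array left out. The acyl-CoA thioesterases (Acot) had 9 of 12 genes higher (5 to 10 over the scalings, adjusted p = 4.62e-06 and up to 0.0270), among them Acot3 (3.00 ± 0.23) and Acot4 (2.77 ± 0.25), and 2 higher in the mesenchyme. The claudins of tight junctions (Cldn) had 9 of 24 (8 to 9, adjusted p = 0.00554 and up to 0.0474), led by Cldn8 (4.70 ± 0.26), Cldn7 (4.33 ± 0.24), Cldn23 (3.80 ± 0.24) and Cldn2 (3.60 ± 0.23), and also 2 higher in the mesenchyme. Mfsd carriers had 8 of 21 (8 to 10, adjusted p = 0.0107, at most 0.00421 over the scalings and 0.0175 with an array left out), and 1 higher in the mesenchyme. Solute carriers (Slc) had 88 of 347 (73 to 108, adjusted p = 1.09e-19 and up to 1.16e-17), with 36 higher in the mesenchyme and a median that changed sign under spike-in scaling of all 6 arrays. The list of 342 solute carriers, however, did not pass camera with an estimated correlation (adjusted p = 0.629) or fry (adjusted p = 0.0592). The other 4 families lost the enrichment under some scalings and without some arrays. Tmem had 32 of 218 genes higher (22 to 43 over the scalings, adjusted p = 0.0378 and up to 0.342), with 31 higher in the mesenchyme, and did not pass without epithelium B. Atp had 16 of 77 (7 to 23, adjusted p = 0.0233 and up to 0.917) with 6 higher in the mesenchyme, hydroxysteroid dehydrogenases (Hsd) 7 of 18 (4 to 7, adjusted p = 0.0211 and up to 0.363) and glucuronosyltransferases (Ugt) 5 of 11 (5 under each, adjusted p = 0.0386 and up to 0.138). Tmem passed under 3, Atp under 2, Ugt under 1 and Hsd under 0 of the scalings. Of the 6 fits with an array left out, Atp passed in 3, without epithelium A, epithelium C or mesenchyme A, Hsd in 2, without epithelium A or epithelium C, and Ugt in 4, all but those without epithelium A or mesenchyme C.

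In the mesenchyme, 2 families passed in the deposited values, under each of the 5 scalings and with each array left out. The extracellular proteases of the Adamts family had 10 of 15 genes higher (10 to 11 over the scalings, adjusted p = 0.00139 and up to 0.00232, 0.00652 with an array left out), including Adamts1 (3.40 ± 0.24) and Adamts9 (2.83 ± 0.23). Collagens had 27 of 42 (24 to 28, adjusted p = 5.20e-10 and up to 8.05e-08), a list that did not pass camera with an estimated correlation (adjusted p = 0.197). Zinc finger genes (Zfp) had 88 of 337 (57 to 117, adjusted p = 0.000114 and up to 0.113), with 5 higher in the epithelium, and passed with each array left out (69 to 111 genes) and under 4 scalings. Mmp genes had 9 of 18 (6 to 9, adjusted p = 0.0378 and up to 0.218), septins 7 of 12 (4 to 8, adjusted p = 0.0378 and up to 0.449) and Kelch-like genes (Klhl) 13 of 33 (8 to 15, adjusted p = 0.0378 and up to 0.421). With an array left out, Mmp passed without epithelium A or mesenchyme A, septins without epithelium C or mesenchyme A and Klhl without epithelium A, epithelium B or mesenchyme A. Septin passed under 1 of the scalings and Mmp and Klhl under 0.

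More genes were higher in the mesenchyme than in the epithelium, and an offset between the arrays of the tissues cannot be told apart from a true difference in the number of genes that each tissue expresses, which was not tested. The scalings on controls or on 1 class of genes went apart: 50.72% of the changed genes were higher in the mesenchyme with equal ribosomal protein genes, 77.5% with equal spike-in controls and 66.8% with these and mesenchyme B left out, against 66.0% in the deposited values. Equal medians, the test first set for an offset, gave 49.43%, but they even out the calls by themselves and decide nothing. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many changed genes (4380, highest other 0), changed probe sets (9671, highest other 0) and lists (34, highest other 31). With 10 splits no share can fall under 0.05. Each other split also mixed both tissues within its groups, which widened the spread there and left part of the tissue difference in the contrast. The splits therefore decide nothing about chance.

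Abundant epithelial genes were higher in mesenchyme C than in the mean of mesenchyme A and B, with 52 of 58 genes above it and a median excess of 0.325 on the log2 scale. More epithelial tissue carried over into that pool may be the cause: the median excess in the 4 lists was 1.34% to 1.97% of the epithelial level, a ratio of 1.467 between the highest and the lowest. Single genes spread more widely. The quartiles were 0.69% and 2.10% for the brush border, 1.15% and 5.11% for lipid genes, 0.75% and 2.20% for transporters and 1.08% and 2.13% for junctions. Similar list medians therefore do not show 1 constant fraction. The 6 genes without an excess keep carry-over open, since it would raise all of the genes and noise of single arrays could hide it. An offset of the whole array is argued against by the median excess of all genes, which was 0, and by that of the matrix genes, which was -0.15. No biological explanation was tested.

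Of 5 heat shock genes, 3 were higher in the mesenchyme (Hspa1a, Hspa1b and Hspb1). The 3' minus 5' control values of Gapdh and beta-actin, both near the top of the range, differed between tissues by 0.0667 at most. Dimmer controls lay further apart in the epithelium. Pyruvate carboxylase averaged 10.03 (3') and 9.17 (5') there, and 8.97 and 8.93 in the mesenchyme. The transferrin receptor averaged 9.37 and 7.30 in the epithelium, and 7.03 and 5.83 in the mesenchyme. Both transcripts were also lower in the mesenchyme, by 1.07 and 2.33 at the 3' probe sets. The mesenchymal 5' value of the transferrin receptor lay within the range of the bacterial controls (5.47 to 5.98 per array). These dimmer controls thus cannot separate RNA quality from expression level, and degradation of messenger RNA in one tissue stays open. The 3' and 5' values of 18S ribosomal RNA lay further apart in the mesenchyme (1.20 ± 0.96) than in the epithelium (0.23 ± 0.12). They did not overlap between tissues (chance 10%), so that another difference in RNA quality stays open as well. A response to the hours of separation may contribute. The other 25 genes of the immediate early and heat shock list also hold Hmox1 and Ddit3. Of these 25, 5 were higher in the mesenchyme and 1 was higher in the epithelium. Over all 18161 genes, 2892 were higher in the mesenchyme and 1488 in the epithelium. A stress response can therefore not be told apart from a difference between the tissues, which were handled in one procedure.

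The Hox genes called higher in the mesenchyme may follow their order in the clusters, a hypothesis found and tested on the same data. Of 19 genes in paralog groups 1 to 8, 12 were higher in the mesenchyme, against 0 of 14 in groups 9 to 13 (10 to 13 against 0 over the 5 scalings, 10 to 12 against 0 with an array left out; Fisher's exact test, two-sided, p = 0.0001618 and up to 0.00142, where genes of a cluster are not independent). The median mesenchymal level was 9.87 in the first set and 7.50 in the other, so that low signal could also have hidden differences in groups 9 to 13. In group 9, Hoxa9, Hoxb9 and Hoxc9 were within 0.13 of 0, but Hoxd9 differed by 0.63 towards the mesenchyme (adjusted p = 0.0243, under 2-fold).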
